A study of Mus musculus with 6 samples.

How the data were processed

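Glomeruli of 6 mouse samples were profiled by RNA sequencing, 3 labelled Cre-/Setdb2fl/fl and 3 Cre+/Setdb2fl/fl, all labelled as diabetic kidney disease. The diabetes model, the Cre driver, the age and the sex of the mice are not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected, and strand-marked libraries made with dUTP were sequenced as read pairs on an Illumina NovaSeq instrument. The submitters' processing notes name fastp, HISAT2, StringTie, edgeR and the genome build GRCm39, without versions, roles or order. The authors deposited 1 table of whole-number read counts per Ensembl gene for all 6 samples. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. StringTie can derive counts from coverage and round them, and reads with several matches can be counted at each copy, so counts of near-identical genes, of overlapping genes and of genes at 0 in 1 genotype are uncertain. Nearly equal counts of mitochondrial genes and their nuclear copies are given with the results.

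Gene symbols came from a table that pairs Ensembl identifiers with symbols, which covered 51880 of 57132 gene rows. Of the 19927 genes tested, 606 had no symbol, 16 of them among those changed. The annotation at hand was GENCODE M21 on GRCm38, another build than the submitters' notes name, so no coordinates are printed and it served only for names, chromosomes and which genes overlap. Symbols of list genes that had been renamed were looked up among RefSeq synonyms. Where a symbol had several identifiers, the one with the highest total count stood for it in a list.

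The counts were analysed as deposited with R 4.3.3 and edgeR 4.0.16. Genes were kept with filterByExpr and TMM factors were computed. The genotypes were compared with edgeR's quasi-likelihood test (robust=TRUE) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the test's F. CPM values are scaled by the TMM factors, which ranged from 0.979 to 1.03. Setdb2 and Smad3 were also tested with a two-sided exact permutation test of log2 CPM over 10 distinct splits, whose smallest p is 0.1. Total counts ranged from 53571438 to 58807042 per library, and the square root of the common dispersion was 21.5%. For each pair of libraries, a chi-square statistic per degree of freedom was computed over genes with at least 50 counts summed over all libraries. It was 20.6 or more, so no pair differed as little as sampling noise would give. Intervals are given at 95%. The floor of 3 counts per library covers counting error only.

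The 28 gene lists, the rule for named genes, the tests and the other settings were fixed before the data were examined. The rule named Setdb2 and Smad3, the 10 largest rises and the 10 largest falls among genes past the threshold with an average log2 CPM of at least 1, no overlap between genotypes and an assigned symbol (no Gm, LOC or Rik name), and up to 4 members per list by smallest p among those past the threshold. Some genes that the rule takes are not reported here. Where no member of a list passed, the member with the smallest p was named as not passing. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Counts called adjusted over the list alone take Benjamini-Hochberg values within the list.

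The test was checked on simulated counts drawn from the means, library sizes and dispersion of these samples for the comparison of Cre_positive with Cre_negative. Of the genes changed by known folds, 29.9% at 1.5-fold, 65.7% at 2-fold and 93.9% at 4-fold were called among 19450 genes, and 8.39% of all calls were unchanged genes, above the nominal 5%. A shifted list passed camera and 0 of 27 unshifted lists did. The simulated genes were drawn independently of each other, so this could not test the preset correlation. In the data the estimated correlation reached 0.912, for the cell cycle list. The other settings were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma voom with quality weights, robust=FALSE, other filters on low counts and other thresholds. Further ones were a replicate block, proximal tubule or podocyte markers as a covariate, each library left out, camera with an estimated correlation, and fry. A second list of p53 targets and 9 gene families in the closing section were chosen after the first results were seen. Exon-level deletion of Setdb2 was not analysed here.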

Results

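RNA sequencing was carried out on glomeruli, the filtering units of the kidney, isolated from mice labelled as having diabetic kidney disease. All 6 samples carried floxed Setdb2 alleles. The Cre recombinase was absent from 3 samples (Cre_negative) and present in 3 (Cre_positive). Per the series' design text, the comparison addresses the part that SETDB2 of podocytes, a putative histone H3 lysine 9 methyltransferase, has in this disease. Podocytes are the epithelial cells that cover the glomerular capillaries. The libraries held between 53571438 and 58807042 counts, and 31243 of 57132 gene rows had a count in at least 1 library. Mitochondrially encoded genes took 8.40% to 10.2% of the counts. In a principal component analysis of log2 CPM, the first component held 40.6% of the variance and separated the genotypes, with Cre_negative libraries at -62.1, -45.3 and -24.5 and Cre_positive libraries at 42.9, 45.8 and 43.2. The labels do not say that the replicates came from separate mice, so p-values measure the spread between these samples. That spread may be technical in part. Xist, the RNA that silences an X chromosome in female cells, had 36474 to 47632 counts in 5 libraries and 24 counts in Cre_positive replicate 2. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in all 6. The Xist counts argue against Cre_positive replicate 2 being a technical copy of another library. For the other libraries the question stays open.

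Setdb2 (ENSMUSG00000071350), the targeted gene, was not measurably lower in the Cre_positive libraries. Its counts were 591, 492 and 370 in Cre_negative replicates 1, 2 and 3 and 427, 444 and 391 in the Cre_positive ones, or 8.37 ± 1.62 against 7.70 ± 0.371 CPM (SD, n = 3). The log2 fold change of -0.12 (SE 0.18) had a 95% confidence interval of -0.52 to 0.28, which allows between 0.697 and 1.21 times the Cre_negative level, and the adjusted p was 0.738. A two-sided exact permutation test of log2 CPM gave p = 0.6, where the smallest p that 3 against 3 samples allow is 0.1. The labels do not say which part of the gene is deleted. Podocytes are 1 of the cell types in a glomerulus, and the isolates also held abundant tubule RNA, as given below. These gene-level counts therefore do not check the genotype labels. Smad3 (ENSMUSG00000032402), which encodes the signal transducer of TGF-beta that the series title names as a silenced target, had 62.8 ± 1.97 CPM in Cre_negative and 73.8 ± 7.42 CPM in Cre_positive libraries (SD, n = 3). All 3 Cre_positive libraries lay above the Cre_negative ones, with a log2 fold change of 0.23 (SE 0.085, 95% confidence interval 0.04 to 0.43), but the adjusted p of 0.140 did not pass the threshold and the exact p was 0.1, the smallest this design can give.

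**Figure D1:**
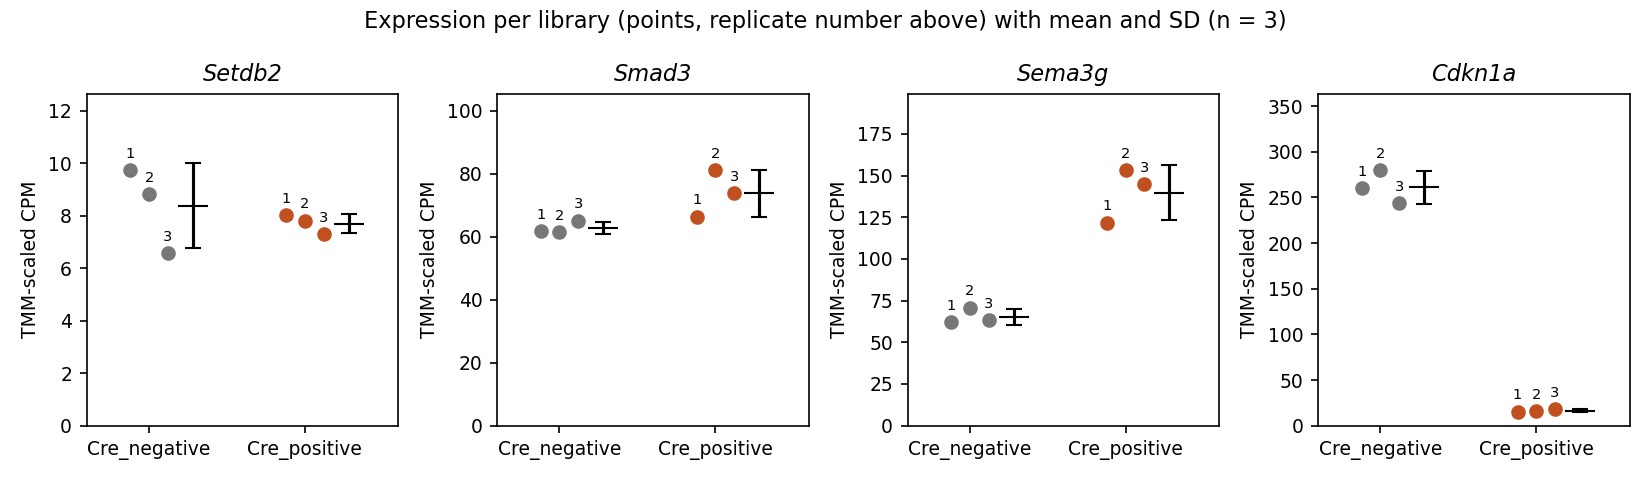
Expression of Setdb2, Smad3, Sema3g and Cdkn1a in TMM-scaled CPM in each library, grey for Cre_negative and orange for Cre_positive, with the replicate number above each point and the mean and SD of 3 libraries as a black bar. The Setdb2 values of the genotypes overlap, Sema3g averages 65.4 against 139.8 CPM, and Cdkn1a averages 261 against 16.4 CPM.

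The kidney injury gene Havcr1, the p53 target Cdkn1a and complement C3 were among the largest falls in the Cre_positive libraries. Kap, an androgen-regulated gene of the proximal tubule, was among the largest rises. Havcr1 encodes the tubular injury marker KIM-1 and went from 113 ± 141 to 0.410 ± 0.165 CPM (SD, n = 3), a log2 fold change of -8.10 (SE 1.55) with an adjusted p of 0.0481. Cdkn1a, the p21 cell cycle inhibitor induced by p53, fell from 261 ± 18.1 to 16.4 ± 1.40 CPM, a log2 fold change of -4.00 (SE 0.096, adjusted p = 4.06e-07). Eda2r, a receptor of the tumour necrosis factor family, had a log2 fold change of -5.29 (SE 0.22), the injury keratin Krt20 -4.69 (SE 0.75), and the protease inhibitor Timp1 -4.54 (SE 0.82). The log2 fold change was -4.41 (SE 0.76) for the glucuronosyltransferase Ugt2b37, -4.24 (SE 0.53) for the neutrophil chemokine Cxcl1, -4.12 (SE 0.24) for Psrc1, -4.08 (SE 0.65) for the serpin Serpina10 and -3.89 (SE 0.55) for C3. Among the rises, Kap went from 244 ± 177 to 6372 ± 686 CPM, a log2 fold change of 4.71 (SE 0.59, adjusted p = 0.0132). The sulfatase Arsi followed at 4.02 (SE 0.64), then Rdh19 at 3.24 (SE 0.45), the branched-chain aminotransferase Bcat1 at 2.90 (SE 0.35) and Angptl7 at 2.90 (SE 0.41). The lipid transporter Mfsd2a stood at 2.68 (SE 0.42), Slitrk1 at 2.28 (SE 0.33), Adgrg4 at 2.25 (SE 0.39) and Asxl3 at 2.23 (SE 0.36). Tprg had 0 counts in the Cre_negative libraries and 156 to 331 in the Cre_positive ones, at least 79.1-fold higher against a floor of 3 counts per library. Such an all-or-none value can also come from how reads were assigned to gene models, so it is uncertain.

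In all, 1505 of 19927 genes tested (7.55%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 743 higher and 762 lower in Cre_positive. At least 2-fold changes were found for 189 higher and 317 lower genes, and at least 8-fold changes for 11 higher and 62 lower genes. The genotypes did not overlap for 5912 genes (29.7%), where chance gives 10%. The count rested in part on the Cre_positive libraries, at 700 without replicate 1, 605 without replicate 2 and 462 without replicate 3. Leaving out any 1 of the Cre_positive libraries ended the calls of Havcr1 (adjusted p up to 0.151), Krt20 (0.0811), Timp1 (0.106), Ugt2b37 (0.0994) and Serpina10 (0.0880), and for Havcr1 and Krt20 so did leaving out Cre_negative replicate 2. The call of C3 ended without replicate 1 or 2 of either genotype (0.0885), and that of Arsi without Cre_negative replicate 3 or Cre_positive replicate 2 or 3 (0.0570). Without Cre_negative replicate 1 the calls of Rdh19 (0.0710), Bcat1 (0.0622) and Mfsd2a (0.0541) ended, that of Rdh19 also without Cre_negative replicate 2.

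**Figure D2:**
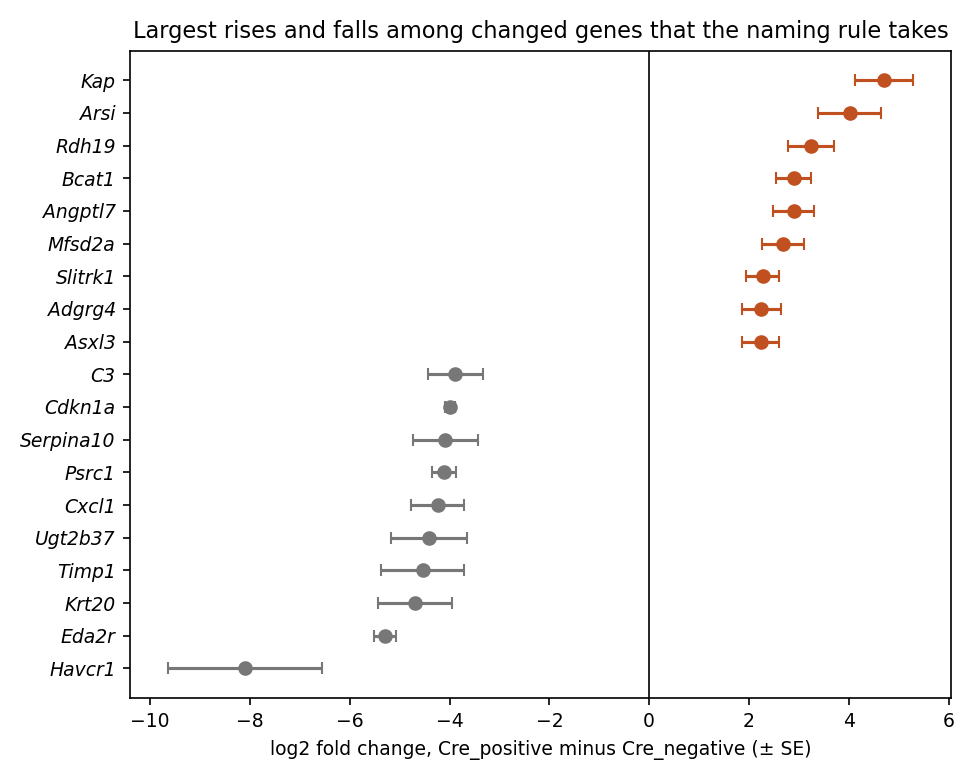
Fitted log2 fold change, Cre_positive minus Cre_negative, of the genes with the largest rises (orange) and falls (grey) among those past the threshold that had an assigned symbol, an average log2 CPM of at least 1 and no overlap between genotypes, with bars of 1 SE. Genes with only a Gm, LOC or Rik name were not ranked. Tprg is left out because its fold is only a lower bound; Havcr1 has the widest error, an SE of 1.55, and Cdkn1a the narrowest, 0.096.

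The list of p53 and apoptosis genes passed the set test pointing down in Cre_positive. Of the 18 members tested, 10 fell, 1 rose and 7 did not pass (13 lower and 1 higher adjusted over the list alone). The median log2 fold change was -0.53 and the adjusted p in the set test 2.74e-07 (adjusted p = 0.123 with an estimated correlation). Besides Cdkn1a, Mdm2, the ubiquitin ligase that p53 induces, changed by -1.17 (SE 0.071, adjusted p = 7.83e-05), and the pro-apoptotic BH3-only genes Pmaip1 and Bbc3 changed by -1.56 (SE 0.15) and -1.77 (SE 0.19). Cell cycle genes had a median of -0.90 and an adjusted p of 0.000889 in the set test (adjusted p = 0.521 with an estimated correlation), although none of the 23 passed singly: Rrm2, the ribonucleotide reductase subunit with the smallest p, stood at -1.41 (SE 0.39) with an adjusted p of 0.0876. Rrm2 passed without Cre_negative replicate 1 or 3 (adjusted p down to 0.0259). It also passed with the replicate block (0.0150), DESeq2 (0.0180), limma voom (0.0491) and robust=FALSE (0.0455). Its log2 fold change ranged from -1.66 to -0.86 when single libraries were left out. The mean log2 CPM of the cell cycle list was 4.40 in Cre_negative replicate 1, against 3.12 and 2.68 in replicates 2 and 3 and 3.00, 2.55 and 2.64 in the Cre_positive libraries. Without Cre_negative replicate 1 the cell cycle list no longer passed (adjusted p = 0.0653, median -0.20).

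The lists of injured epithelium, of inflammatory cytokines and of the interferon response passed the set test pointing down, with most members of each not passing singly. In the list of parietal and injured epithelium, 6 of 14 members fell, none rose and 8 did not pass (12 lower and 1 higher adjusted over the list alone). Its median was -1.35 and its adjusted p in the set test 4.14e-06 (adjusted p = 0.385 with an estimated correlation). Beside Krt20, the keratins Krt18 and Krt8 changed by -1.27 (SE 0.22) and -0.68 (SE 0.13), and the surface marker Cd24a by -0.44 (SE 0.088). The mean log2 CPM of this list was 6.70, 5.81 and 5.54 in Cre_negative replicates 1, 2 and 3 and 4.11, 4.40 and 4.05 in the Cre_positive ones. Of 21 NF-kB and cytokine genes, 8 fell, 1 rose and 12 did not pass (11 lower and 1 higher adjusted over the list alone). Its median was -0.75 and its adjusted p in the set test 4.22e-06 (adjusted p = 0.385 with an estimated correlation). The T cell chemokine Cxcl10 changed by -2.36 (SE 0.24), the macrophage growth factor Csf1 by -0.75 (SE 0.12) and Nfkb2 by -0.68 (SE 0.12). Of 22 interferon response genes, 9 fell, none rose and 13 did not pass (20 lower and 1 higher adjusted over the list alone). Its median was -0.92 and its adjusted p in the set test 1.85e-09 (adjusted p = 0.389 with an estimated correlation). Bst2, which tethers virus particles to cells, changed by -1.36 (SE 0.13), Ifit3 by -0.86 (SE 0.11) and the RNA sensor gene Ddx58 by -0.66 (SE 0.11).

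The macrophage and MHC class II lists passed the set test pointing down, with few members past the threshold. Of 17 macrophage and monocyte genes, 2 fell, none rose and 15 did not pass (7 lower adjusted over the list alone). Its median was -0.78 and its adjusted p in the set test 0.000275 (adjusted p = 0.462 with an estimated correlation). The 2 were the complement subunit C1qc at -1.25 (SE 0.23) and the lipopolysaccharide co-receptor Cd14 at -2.07 (SE 0.44). The mean log2 CPM of the macrophage list was 4.06 and 3.52 in Cre_negative replicates 1 and 3 but 2.75 in replicate 2, close to the Cre_positive libraries, the highest of which stood at 2.72. Of 9 MHC class II genes, H2-DMb1 alone fell, by 0.80 on the log2 scale (SE 0.11), and 8 did not pass (3 lower adjusted over the list alone). Its median was -0.66 and its adjusted p in the set test 0.0130 (adjusted p = 0.514 with an estimated correlation). The MHC class II list mean was 3.34 in Cre_negative replicate 2, below the 3.61 to 4.03 of the Cre_positive libraries, and the list did not pass without Cre_negative replicate 1 or without replicate 3 (adjusted p up to 0.123, with a median of -0.38 without replicate 3). Lymphocyte and neutrophil genes did not pass as a list (adjusted p = 0.476, and 0.795 with an estimated correlation), and none of 16 passed singly. The B cell receptor component Cd79a had the smallest p there, at 2.01 (SE 0.53) with an adjusted p of 0.0553; it did not pass, except with DESeq2 (adjusted p = 0.0349). Leaving out any 1 of the Cre_positive libraries ended the calls of Cd24a (adjusted p up to 0.103), C1qc (0.0893), Cd14 (0.140) and Nfkb2 (0.0694), and leaving out Cre_positive replicate 2 or 3 those of Csf1 (0.0534) and Ddx58 (0.0615). Krt18 (0.0726) and Krt8 (0.0868) lost theirs without Cre_positive replicate 1 or 3, and these and Cd14 also without Cre_negative replicate 2.

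The podocyte, glomerular endothelial, mesangial, and vascular smooth muscle and renin lists all passed the set test pointing up in Cre_positive libraries. Of 31 podocyte genes, 11 rose, 1 fell and 19 did not pass (20 higher and 1 lower adjusted over the list alone). Its median was 0.40 and its adjusted p in the set test 9.05e-08 (adjusted p = 0.123 with an estimated correlation). The semaphorin Sema3g went from 65.4 ± 4.77 to 139.8 ± 16.3 CPM (SD, n = 3), a log2 fold change of 1.10 (SE 0.099, adjusted p = 0.000679). Rhpn1 changed by 0.86 (SE 0.091) and the guidance receptor Robo2 by 0.81 (SE 0.099). Of 21 glomerular endothelial genes, 12 rose, none fell and 9 did not pass (15 higher adjusted over the list alone). Its median was 0.55 and its adjusted p in the set test 8.90e-08 (adjusted p = 0.123 with an estimated correlation). Robo4 changed by 0.87 (SE 0.13), the adherens junction cadherin Cdh5 by 0.69 (SE 0.074), Emcn by 0.63 (SE 0.065) and the endothelial adhesion molecule Pecam1 by 0.59 (SE 0.069). Of 12 mesangial genes, 4 rose, 1 fell and 7 did not pass (6 higher and 1 lower adjusted over the list alone). Its median was 0.33 and its adjusted p in the set test 0.00300 (adjusted p = 0.385 with an estimated correlation). Sfrp2, a secreted Wnt modulator, changed by 1.86 (SE 0.29), the integrin Itga8 by 0.83 (SE 0.11) and the growth factor receptor Pdgfrb by 0.60 (SE 0.091), while the protease inhibitor Serpine2 changed by -1.32 (SE 0.17). Of 12 vascular smooth muscle and renin genes, 2 rose, none fell and 10 did not pass, which was the same adjusted over the list alone. Its median was 0.41 and its adjusted p in the set test 0.00311 (adjusted p = 0.385 with an estimated correlation). Rgs5, a pericyte regulator of G protein signalling, changed by 0.45 (SE 0.090) and Smtn by 0.43 (SE 0.11). Both calls ended without any 1 of the Cre_positive libraries and without Cre_negative replicate 1 (adjusted p up to 0.0824 and 0.159). Rgs5 lost its call also without Cre_negative replicate 2 and Smtn without replicate 3, and this list did not pass without Cre_negative replicate 3 (adjusted p = 0.103).

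Both lists of tubule markers passed the set test pointing up, with most members of each not passing singly. Of 29 proximal tubule genes, 10 rose, none fell and 19 did not pass (16 higher and 3 lower adjusted over the list alone). Its median was 0.34 and its adjusted p in the set test 4.03e-05 (adjusted p = 0.385 with an estimated correlation). Lrp2, the endocytic receptor megalin, went from 1289 ± 72.6 to 2286 ± 130 CPM (SD, n = 3), a log2 fold change of 0.83 (SE 0.091, adjusted p = 0.00179). The amino acid transporter Slc7a7 changed by 0.89 (SE 0.096), the lactate transporter Slc5a12 by 0.80 (SE 0.12) and the brush border dipeptidase Dpep1 by 0.68 (SE 0.079). Among those lower adjusted over the list alone, and named after their values were seen, were Slc22a6 at -0.71 (SE 0.18) and Pck1 at -0.96 (SE 0.28). Of 19 genes of the loop of Henle, distal tubule and collecting duct, 6 rose, 1 fell and 12 did not pass (6 higher and 2 lower adjusted over the list alone). Its median was 0.11 and its adjusted p in the set test 0.0491 (adjusted p = 0.389 with an estimated correlation). Umod, the uromodulin gene of the thick ascending limb, changed by 0.99 (SE 0.15), the chloride and bicarbonate exchangers Slc4a1 and Slc26a4 by 0.99 (SE 0.15) and 0.99 (SE 0.16), and the thiazide-sensitive cotransporter Slc12a3 by 0.58 (SE 0.11). Slc12a3 lost its call without any 1 of the Cre_positive libraries (adjusted p up to 0.0851) and Slc26a4 without Cre_negative replicate 2 (0.0594). The mean log2 CPM of the proximal tubule list was 8.43, 8.64 and 8.63 in Cre_negative replicates 1, 2 and 3. It was 8.96, 9.06 and 9.21 in the Cre_positive ones, against 5.06 to 5.54 for the podocyte list over the 6 libraries. Tubule RNA was thus abundant in all 6 isolates, although means of different genes do not give the share of each tissue. A change in a gene that both tissues express cannot be assigned to either. The list of the loop, distal tubule and collecting duct did not pass without Cre_negative replicate 1 or 3 or without Cre_positive replicate 1 or 2 (adjusted p up to 0.137). Nor did it pass with a filter of at least 1 CPM in 3 libraries (0.05965) or with the replicate block (0.0853). Its median was 0.067 without Cre_negative replicate 1 and 0.21 without replicate 3.

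Among the other cell types that an isolate can hold, 6 red blood cell genes had a median of 1.46 and an adjusted p of 0.0491 (adjusted p = 0.514 with an estimated correlation). The single call in this list went the other way: Slc25a37, the mitochondrial iron importer mitoferrin, changed by -0.37 (SE 0.092), 5 members did not pass, and adjusted over the list alone 1 was higher and 1 lower. The red blood cell list mean ranged from 3.59 to 4.86 in Cre_negative and from 4.93 to 6.08 in Cre_positive libraries, and the list did not pass without Cre_negative replicate 1 or 2 or without Cre_positive replicate 3 (adjusted p up to 0.122, with a median of 0.94 without the last), nor with at least 1 CPM in 3 libraries (0.05965). Of 4 adipocyte genes tested from 10, 2 fell, none rose and 2 did not pass, the same adjusted over the list alone. Its median was -0.76 and its adjusted p in the set test 0.0258 (adjusted p = 0.389 with an estimated correlation). The hormone-sensitive lipase Lipe changed by -0.78 (SE 0.083) and the lipid droplet protein Cidec by -3.46 (SE 0.80). The adipocyte list did not pass without any 1 of the Cre_negative libraries or without Cre_positive replicate 3 (adjusted p up to 0.245), and its median was -0.28 without Cre_negative replicate 2. It did not pass either with at least 1 CPM in 3 libraries (adjusted p = 0.137), with no filter on low counts (0.503) or in DESeq2 (0.158), and under the last pair of settings its median was above 0, at 0.22 and 0.21. Fibroblast genes did not pass as a list (adjusted p = 0.323, and 0.521 with an estimated correlation): 2 of 11 rose and 9 did not pass, which was the same adjusted over the list alone. These were the collagen Col14a1 at 1.10 (SE 0.14) and Clec3b at 2.37 (SE 0.48). Without single libraries the calls of Slc25a37 (adjusted p up to 0.154, each library except Cre_negative replicate 3), Cidec (0.135, Cre_negative replicates 1 and 2 and Cre_positive replicates 2 and 3) and Clec3b (0.103, Cre_positive replicates 2 and 3) ended.

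TGF-beta genes were examined because the series title names SMAD3. Of 18 pathway components, Ltbp1, a binding protein of latent TGF-beta, was higher at 0.75 (SE 0.17), Ltbp3 was lower at -0.24 (SE 0.061) and 16 did not pass (7 higher and 2 lower adjusted over the list alone). The list did not pass the set test, with a median of 0.22 and an adjusted p of 0.136 (0.521 with an estimated correlation). Of 20 TGF-beta and SMAD3 response genes, 1 rose, 2 fell and 17 did not pass (2 higher and 2 lower adjusted over the list alone). Skil, a feedback inhibitor of SMAD signalling, changed by 0.47 (SE 0.084), and Timp1 and the cyclin-dependent kinase inhibitor gene Cdkn2b by -4.54 (SE 0.82) and -1.32 (SE 0.28). The response list had a median of 0.24 but a mean of -0.17, so these differ in sign, and it did not pass (adjusted p = 0.313, and 0.557 with an estimated correlation). Without Cre_negative replicate 1 the response list passed, pointing up (adjusted p = 0.0196), and without Cre_positive replicate 2 its median was 0.11 and it did not pass (0.564). The extracellular matrix list passed the set test pointing up, with 9 of 36 higher, 3 lower and 24 not passing (15 higher and 4 lower adjusted over the list alone). Its median was 0.48, its mean 0.21 and the adjusted p 0.000652 (adjusted p = 0.514 with an estimated correlation, and 0.149 with fry). The mean log2 CPM of this list was 6.34, 5.71 and 5.78 in Cre_negative replicates 1, 2 and 3 and 6.26, 6.23 and 6.14 in the Cre_positive ones, so Cre_negative replicate 1 lay above every Cre_positive library. The elastic fibre gene Eln changed by 1.67 (SE 0.14, adjusted p = 0.000535), and the basement membrane genes Nid1, Nid2 and Hspg2 by 1.01 (SE 0.14), 0.64 (SE 0.072) and 0.63 (SE 0.090). Without single libraries the calls of Ltbp1 (adjusted p up to 0.129, each library except Cre_negative replicate 3), Ltbp3 (0.159, each of the 6), Skil (0.0779, Cre_positive replicate 3) and Cdkn2b (0.112, Cre_negative replicate 3 and Cre_positive replicates 1 and 3) ended.

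Of the metabolic lists, those of fatty acid oxidation and glycolysis passed pointing down and the mitochondrially encoded one pointing up. Of 21 fatty acid oxidation genes, 7 fell, none rose and 14 did not pass (9 lower and 2 higher adjusted over the list alone). Its median was -0.30 and its adjusted p in the set test 0.00256 (adjusted p = 0.462 with an estimated correlation). The median was -0.12 without Cre_negative replicate 2, where the list still passed (adjusted p = 0.0161). The dienoyl-CoA reductase Decr1 changed by -0.79 (SE 0.11), the carnitine palmitoyltransferases Cpt1a and Cpt2 by -0.49 (SE 0.078) and -0.68 (SE 0.12), and the trifunctional protein subunit Hadha by -0.45 (SE 0.087). Of 17 genes of glycolysis and the glucose response, 4 fell, 2 rose and 11 did not pass (6 lower and 2 higher adjusted over the list alone). Its median was -0.21 and its adjusted p in the set test 0.000820 (adjusted p = 0.385 with an estimated correlation). Pdk4, a kinase that inhibits pyruvate dehydrogenase, went from 293 ± 12.4 to 46.9 ± 11.2 CPM (SD, n = 3), a log2 fold change of -2.64 (SE 0.17, adjusted p = 0.000288). The glucose-induced gene Txnip changed by -0.78 (SE 0.12), and the glycolytic enzymes Eno1 and Pfkp by -0.69 (SE 0.11) and -0.58 (SE 0.089). The 13 mitochondrially encoded genes passed as a list with a median of 0.18 and an adjusted p of 0.00510 (adjusted p = 0.462 with an estimated correlation), while none passed singly, adjusted over the list alone included. The subunit gene mt-Nd4l had the smallest p at 0.38 (SE 0.11, adjusted p = 0.0681), and it passed only without Cre_negative replicate 3 among the left-out libraries (adjusted p = 0.0248), and with DESeq2 (0.00655) and limma voom (0.0429). These genes are uncertain because near-identical copies carry almost the same counts, a mean of 325690 for Gm28437 against 327662 for mt-Co3. Nuclear oxidative phosphorylation genes did not pass (median -0.04, adjusted p = 0.144, and 0.782 with an estimated correlation), and 1 of 35, the cytochrome c gene Cycs, fell by 0.51 on the log2 scale (SE 0.10). The oxidative phosphorylation list passed without Cre_negative replicate 1 (adjusted p = 0.0123) and with limma voom (0.0193). The calls of Cpt2 (adjusted p up to 0.0679), Hadha (0.0873) and Cycs (0.1005) ended without any 1 of the Cre_positive libraries, that of Cpt1a (0.0510) without replicate 2 and that of Eno1 (0.0574) without replicate 3.

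Among stress genes, 4 of 14 ER stress genes fell, none rose and 10 did not pass (5 lower adjusted over the list alone). Its median was -0.30 and its adjusted p in the set test 0.000889 (adjusted p = 0.385 with an estimated correlation). The pseudokinase Trib3 changed by -1.41 (SE 0.30), asparagine synthetase Asns by -1.38 (SE 0.29), the chaperone Dnajb9 by -0.45 (SE 0.10) and the transcription factor Xbp1 by -0.39 (SE 0.094). Of 21 immediate-early and heat shock genes, 1 fell, 1 rose and 19 did not pass (8 lower and 2 higher adjusted over the list alone). Its median was -0.36 and its adjusted p in the set test 0.0143 (adjusted p = 0.462 with an estimated correlation). These were Btg2, which p53 also induces, at -0.97 (SE 0.14) and the flow-responsive factor Klf2 at 0.88 (SE 0.17). Oxidative stress genes did not pass as a list (median -0.10, adjusted p = 0.0522, and 0.436 with an estimated correlation), yet 5 of 20 fell and 1 rose, the same adjusted over the list alone. This list passed without Cre_negative replicate 1 (adjusted p = 0.0142), and with no filter (0.0432), DESeq2 (0.00282), limma voom (0.0210) and fry (0.0337). Its median was -0.043 without Cre_negative replicate 3, where it did not pass. The regulator Nfe2l2 changed by -0.63 (SE 0.074), haem oxygenase Hmox1 by -0.91 (SE 0.12) and Srxn1 by -0.55 (SE 0.073), while the NADPH oxidase Nox4 changed by 0.77 (SE 0.11). The 18 genes of the H3K9 methylation machinery other than Setdb2 did not pass (adjusted p = 0.779, and 0.887 with an estimated correlation), with the set test pointing up and a median of -0.03, and none passed singly. The demethylase Kdm4b had the smallest p, at 0.23 (SE 0.083) with an adjusted p of 0.141. The immediate-early list did not pass without Cre_negative replicate 3 or without Cre_positive replicate 1 (adjusted p up to 0.0842). The calls of Asns (0.0945), Trib3 (0.111), Dnajb9 (0.126), Xbp1 (0.140) and Klf2 (0.0872) ended without single libraries, Cre_positive replicates 1 and 3 among them for each.

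**Figure D3:**
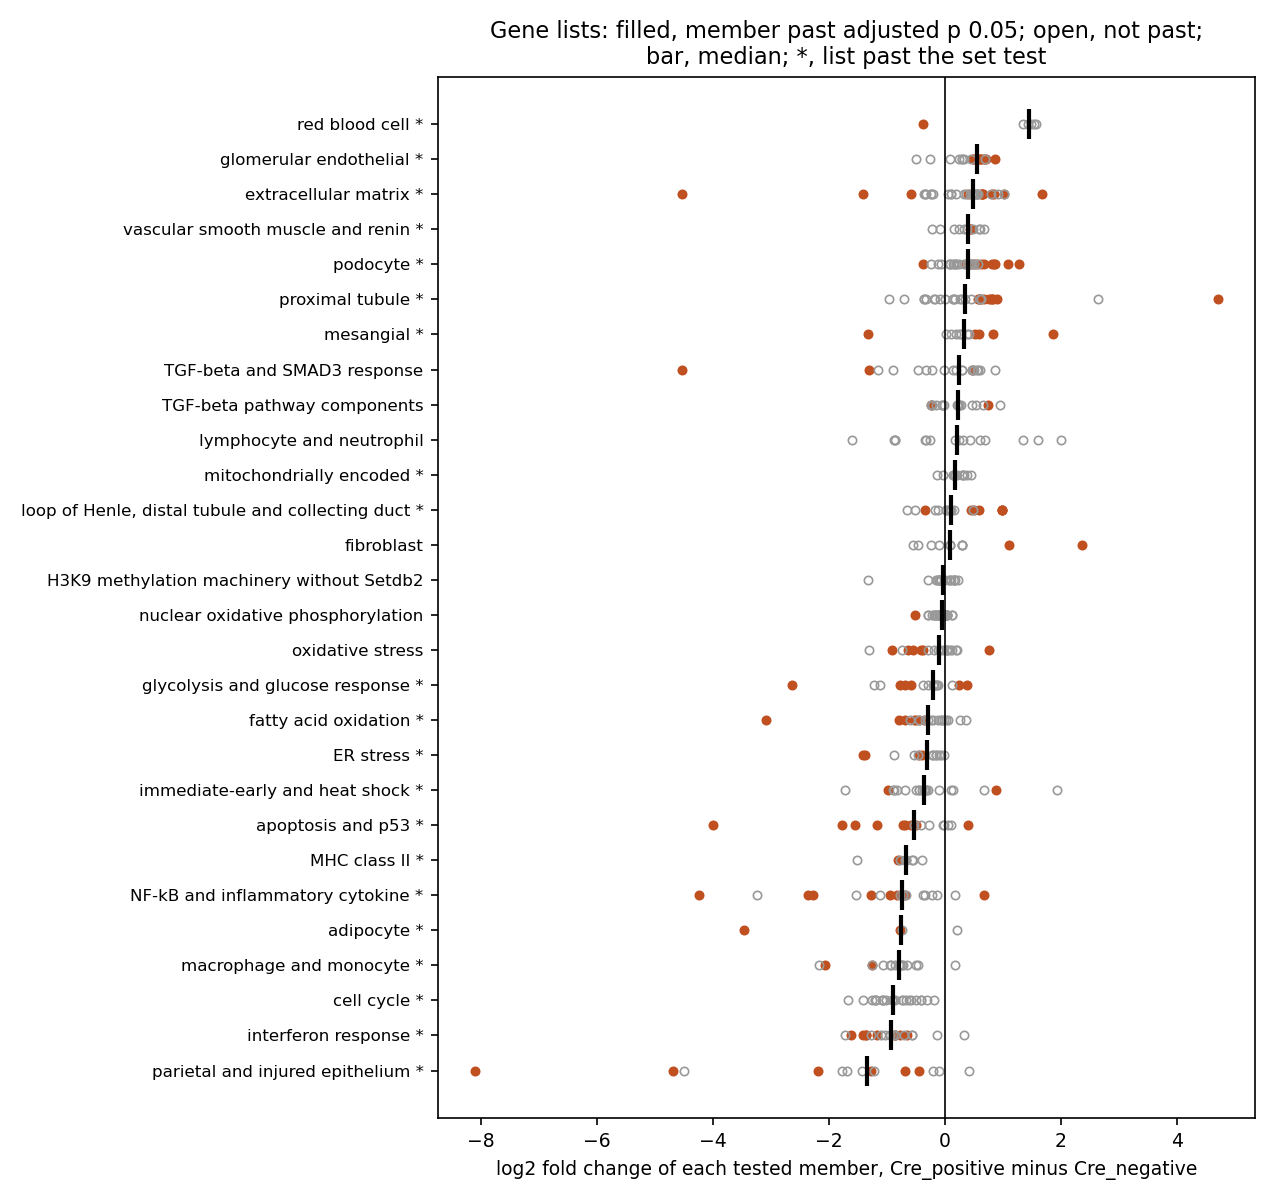
Log2 fold change, Cre_positive minus Cre_negative, of each tested member of the 28 gene lists, filled where the member passed an adjusted p of 0.05 and open where it did not, with a bar at the list's median and a star on lists past the set test. Medians run from -1.35 for parietal and injured epithelium to 1.46 for red blood cell genes.

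Of the 28 lists, 21 passed the set test with a preset correlation of 0.01, 9 higher and 12 lower in Cre_positive. None passed with the correlation estimated from these libraries, where the smallest adjusted p was 0.123, and 12 passed fry, which tests whether a list's genes move on balance one way. The 10 lists that passed camera but not fry were cell cycle, ER stress, immediate-early, fatty acid oxidation, mitochondrially encoded, extracellular matrix, MHC class II, macrophage, red blood cell and smooth muscle (adjusted p from 0.0560 to 0.312). The lists were written from textbook knowledge and some share members, such as Timp1.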

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

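The count of 1505 changed genes stayed within 1.5 times under both other scalings, both other filters, robust=FALSE and limma voom, at 1437 to 1649, and no scaling moved the median of all genes by over 0.1 on the log2 scale. DESeq2 called 2568 genes, 1483 of them shared with the 1505. Thresholds changed the count by construction, to 506 with at least a 2-fold change and 2562 at an adjusted p of 0.1. Leaving out 1 library gave 462 to 2039 genes, with 447 shared at the lowest. Of 88 named genes past the threshold, 79 kept their call under each alternative other than the covariates and the left-out libraries, and 49 kept it without each single library. Beside the 79, the 9 that lost their call under another setting were Havcr1, Cd14, Ugt2b37 and Ltbp3 (no filter), Arsi, C3, Havcr1, Slc25a37 and Ltbp3 (replicate block), Rdh19, Havcr1, Smtn, Slc25a37 and Ltbp3 (limma voom), and Smtn, Slc25a37 and Ltbp3 (robust=FALSE), and the cause was not tested. The fits without a Cre_positive library had 2 samples in that genotype. The replicate block gave 1541 genes (1251 shared) and 20 lists. The numbers do not pair the samples by design. Same-numbered libraries correlated across genes in their deviations at 0.0547, 0.0551 and 0.0173. Each library correlated best with its own number, but Cre_negative replicate 3 reached 0.017 with Cre_positive replicate 2. Values this small and close cannot show whether the libraries were paired.

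The number of lists past the set test was 16 to 20 without single libraries, 18 with at least 1 CPM in 3 libraries, 12 with fry and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Setdb2 ranged from -0.27 to 0.0024 and Smad3 from 0.16 to 0.31 without single libraries, and neither passed in any of these fits; the Setdb2 value above 0 came without Cre_negative replicate 1. List medians ranged from -0.25 to 0.41 for lymphocyte and neutrophil genes (-0.26 with no filter, -0.34 at 1 CPM and -0.27 with DESeq2), from -0.090 to 0.015 for nuclear oxidative phosphorylation and from -0.068 to 0.050 for the H3K9 machinery, with a set test that pointed the other way, without passing, without Cre_negative replicate 2. The fibroblast median ranged from -0.0096 to 0.24, and its set test did not turn.

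With proximal tubule markers as a covariate 14 genes and 11 lists passed, and with podocyte markers 0 genes and 10 lists, in edgeR, with 1075 and 501 genes at an unadjusted p under 0.05. No other tool was run with a covariate. Of the covariates' variance, 86.4% and 96.6% lay between the genotypes, and the median SE was 2.82 and 5.70 times that without a covariate, so these fits can hardly separate marker level from genotype. Signs turned for some results, with no gene of these past the threshold but 3 lists past it, cell cycle with proximal tubule markers and red blood cell and oxidative phosphorylation with podocyte markers. With proximal tubule markers, Setdb2 stood at 0.41, C1qc at 0.029, Cd14 at 0.11 and Rrm2 at 0.58, and list medians were 0.0054 for proximal tubule, 0.29 for macrophage, -0.60 for red blood cell and 1.54 for cell cycle genes. With podocyte markers, Setdb2 stood at 0.98, Bcat1 at -0.036, Krt20 at 4.38, Ugt2b37 at 0.52, Krt18 at 1.09, Krt8 at 0.55, Umod at -0.24, Slc12a3 at -0.20, Cd14 at 0.58, Ltbp1 at -0.14, Skil at -0.21, Cycs at 0.15, mt-Nd4l at -0.44, Eno1 at 0.048 and Btg2 at 0.15. The list medians there were 0.18 for injured epithelium, -0.019 for proximal tubule, -2.05 for lymphocyte and neutrophil, -4.36 for red blood cell, 0.59 for adipocyte, -0.14 for TGF-beta components, 0.46 for nuclear oxidative phosphorylation, -0.12 for mitochondrially encoded, 0.25 for glycolysis and 0.52 for cell cycle genes. For H3K9 genes, at -0.032, only the set test turned. Medians alone turned for NF-kB (0.061) and H3K9 genes (0.14) with proximal tubule markers, and for immediate-early (0.15) and oxidative stress genes (0.0062) with podocyte markers, and none of these passed. In the simulation with 3 samples per genotype, changes of 1.5-fold were mostly missed, with 29.9% of such genes called.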

Other observations

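The gene families and all tests in this part were chosen after the first results were seen, except that the test of the second p53 list and the counts over other splits were written down before their results. Among 9 families counted, all 7 immunity-related GTPases tested fell, with a median log2 fold change of -1.60, among them Igtp at -1.87 (SE 0.16), Irgm1 at -1.47 (SE 0.20) and Irgm2 at -1.30 (SE 0.17). Of 11 guanylate-binding proteins, 6 fell and 5 did not pass, with Gbp2 at -1.97 (SE 0.25) and Gbp6 at -2.02 (SE 0.28). All 8 genes of the immunoproteasome and peptide transport fell, with a median of -0.71, including Tap1 at -1.44 (SE 0.21), Psmb8 at -1.11 (SE 0.15) and Psmb10 at -0.66 (SE 0.10). These 3 families, in the order GTPases, guanylate-binding proteins and immunoproteasome, passed camera with adjusted p of 1.47e-07, 2.83e-05 and 1.59e-07, each with an adjusted p = 0.328 with an estimated correlation. Gbp and Tgtp genes have near-identical copies, so single values are uncertain.

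Solute carriers and cytochrome P450 genes changed member by member. Of 323 solute carriers, 35 rose and 21 fell, with a median of -0.0083. The sodium-phosphate cotransporters Slc34a3 and Slc34a1 rose by 1.72 (SE 0.23) and 0.62 (SE 0.0996), the sodium-glucose cotransporter Slc5a2 by 0.82 (SE 0.14) and the amino acid transporter Slc6a19 by 0.75 (SE 0.11), while the glucose transporter Slc2a2 changed by -0.67 (SE 0.11) and the mitochondrial carrier Slc25a25 by -1.85 (SE 0.30). Of 51 cytochrome P450 genes, 3 rose and 9 fell (camera adjusted p = 0.00702, and adjusted p = 0.328 with an estimated correlation). The vitamin D 24-hydroxylase Cyp24a1 went from 494 to 67.1 mean CPM (log2 fold change -2.88, SE 0.56), and the fatty acid hydroxylases Cyp4a12b and Cyp4a12a changed by -2.72 (SE 0.24) and -2.18 (SE 0.25). Of the other families, 3 of 16 UDP-glucuronosyltransferases, 3 of 12 keratins and 3 of 12 serpin A genes fell, and of 7 aldo-keto reductases of the 1C type 2 fell and 1 rose.

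In the lists of injured epithelium, p53 and NF-kB, 6 of 14, 10 of 18 and 8 of 21 members fell in the Cre_positive libraries, while 1 p53 and 1 NF-kB member rose (adjusted p = 0.385, 0.123 and 0.385 with an estimated correlation). Less proximal tubule marker RNA is argued against as the whole cause. Of 29 proximal tubule genes, 10 rose and none fell (3 lower adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.385 with an estimated correlation). Marker RNA does not count cells, so a difference in the number of proximal tubule cells stays open. A hypothesis that fits the values is lower p53 activity in the Cre_positive samples: a second list of 20 p53 targets, which shares no gene with the fixed lists, had a median of -1.09, with 15 members lower and none higher (camera p = 2.74e-13, and p = 0.00134 with an estimated correlation). Phlda3 at -2.98 (SE 0.11) and Ccng1 at -2.18 (SE 0.11) were among them, while Sesn1 at 0.059 (SE 0.079) and Perp at 0.039 (SE 0.069) did not pass. Interchanged genotype labels cannot be told apart from the labelled order, because Setdb2 at -0.12 has an interval on both sides of 0; the genotype stays open as an untested biological explanation, and p53 activity itself, the severity of diabetes and handling of the isolates were not measured.

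Xist was nearly absent in Cre_positive replicate 2 alone, at 0.421 CPM against 653 to 888 in the others. A male mouse is argued against by a summed count of 0 over 4 Y-linked genes in this library. Of 1545 gene rows on chromosome Y, 8 had a count in any library, a number that is not specific to this one. Loss of the Xist signal alone is argued against by 4 of 4 genes that escape X inactivation lying below all 5 other libraries. A single X chromosome may account for this, as the median ratio of these genes to the mean of the other libraries was 0.670, against 0.983 to 1.13 for each other library, while 322 X-linked genes differed from the other Cre_positive libraries by a median log2 difference of -0.046. Whether the genotype bears on it was not tested. Without this library 605 genes passed in place of 1505, against 700 without Cre_positive replicate 1 and 462 without replicate 3. The drop was thus not particular to this library.

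Gm20716, named here after its values were seen, had 62.9 ± 6.02 CPM in Cre_negative and 0 in Cre_positive libraries (SD, n = 3). In the GRCm38 annotation it overlaps Adnp and Dpm1, which had 70.1 ± 8.26 against 105 ± 1.75 CPM (adjusted p = 0.00739) and 20.9 ± 9.17 against 46.1 ± 4.72 CPM (adjusted p = 0.0698, edgeR). Reads given to the overlapping genes may account for the zeros, because the sum of the 3 genes was 154 ± 6.72 against 151 ± 6.45 CPM, a log2 ratio of -0.024. A change in the genotype remains untested as a biological explanation.

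Other splits of the 6 libraries into 3 and 3 are too few to give a share under 0.05: 1 of 10 splits, the real one, gave 1505 genes, and the highest of the others gave 1 gene. For the gene lists, 1 of 10 splits gave 21 and the others gave 2 to 14. Camera with the preset correlation thus also passed lists in groupings that called at most 1 gene.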
